A study of Mus musculus with 10 samples.

How the data were processed

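Total RNA was measured by RNA sequencing in the dorsal telencephalon of mouse embryos at embryonic day 12. The 10 libraries comprised 5 controls, which carried 1 floxed and 1 wild-type copy of Rnu11, and 5 mutants, in which both copies were floxed. Both groups carried Emx1-Cre, per the labels. The animals were of mixed C57/Bl6 and 129 SvJ background. RNA was extracted with Trizol, and stranded libraries were made after removal of ribosomal RNA with Ribo-Zero, per the labels' protocols. The submitters' processing notes name the aligner HISAT2 and the mouse build GRCm38 (mm10). The program that computed the expression values, its annotation and the use of strand are not given in the sources used here.

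The authors deposited 1 list per library of gene symbols with FPKM values (fragments per kilobase of transcript, scaled to library size). Each list held the same 38803 symbols. The FPKM values of a library summed to between 1996700 and 3051430. Protein-coding genes held 10.1 to 19.1% of these sums and the signal recognition particle and 7SK RNAs 38.6 to 55.4%. The number of fragments per library is not stated. It was estimated from the step that a single fragment adds to the FPKM of single-transcript genes with over 1500 exonic bases, taking the most frequent step, which 38 to 65 of 801 to 1180 genes shared. The estimates are rough and ran from 9650000 fragments in control 4 to 21300000 in mutant 5. At these depths a single fragment in a transcript of 2000 bases is worth 0.0518 FPKM in control 4 and 0.0235 FPKM in mutant 5. These are estimates from the deposited values, so no counting intervals were computed.

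Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes moderation and with genotype as the single term. Genes with at least 1 FPKM in at least 5 libraries were tested, 13522 in all, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. List p-values were adjusted over the lists tested. Medians of lists are given relative to the median of all tested genes, which itself lay at 0.11 on the log2 scale. Levels of single genes and of lists per library were compared by exact two-sided permutation tests over all splits of 5 against 5, for which 0.00794 is the smallest possible p. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

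Gene symbols were matched to the GENCODE M21 annotation of GRCm38. Of the 38803 symbols, 35655 matched by name, 1765 by an older name and 1383 did not match. 80 symbols matched more than 1 gene. Coordinates are those of that annotation, which may differ from the one the authors used. The library kit marks strand, but whether strand was used in counting is not given in the sources used here, so values of genes that overlap a gene on the opposite strand are uncertain. Processed pseudogenes can share reads with their parent genes, and their values are uncertain for the same reason.

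The design, the 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named Rnu11. It named up to 12 genes per direction with the largest log2 change among those past the threshold, with a mean of at least 1 FPKM in the higher group and no overlap between the groups, leaving out predicted genes and pseudogenes. It named up to 4 members past the threshold in each list, or the 2 with the smallest p where none passed, and up to 5 members per direction of the minor-intron list. Minor introns were to be found by sequence motif where a genome sequence was given. No genome sequence was used here, so the list of 37 minor-intron genes from general knowledge, fixed as the fallback, was used.

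The lists were minor spliceosome components, short non-coding RNA comparators, minor-intron genes, p53 targets, apoptosis machinery, radial glia, intermediate progenitors, early excitatory neurons, Cajal-Retzius cells, S phase, G2 and M phase, DNA damage response and repair, integrated stress response, unfolded protein response, interferon-stimulated genes, cortical patterning, ribosomal proteins, major spliceosome proteins, ventral telencephalon, choroid plexus and hem, erythroid cells, endothelial cells, mesenchyme with pericytes and meninges, microglia and macrophages, mitochondrially encoded genes, sex-linked genes and immediate early genes. The sex-linked list had 1 member above the filter and was not tested as a list.

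On data simulated from the means and spreads of the 13522 tested genes, with 200 genes changed, drawn from genes with a control mean over 2 on the log2 scale, the test recovered 44.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 8 false calls. A simulated list of 35 genes shifted by 0.5 log2 was called by camera, and 0 of 100 unshifted lists were. The simulated genes varied independently of each other and without library sets. These rates therefore do not show how often camera calls lists of correlated genes in the real libraries.

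The first principal component of the tested genes (31.9% of the variance) parted control 5, mutant 4 and mutant 5 from the other 7 libraries. No label names a batch. This split crosses genotype and is called the second and first library set below. A fit with the set as a term, and fits within each set, were chosen after seeing the data. Other alternatives were pseudocounts of 0.1 and 0.5, other filters and thresholds, rescaling to a common median ratio, quantile normalization, library quality weights, a fit without a trend, replicate number as a block, the level of Y-linked genes as a covariate, protein-coding genes alone and leaving out each library in turn.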

Results

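Rnu11 encodes the U11 small nuclear RNA, the part of the minor spliceosome that recognises the 5' end of minor introns, a rare class of introns found in a small share of genes. Emx1-Cre drives recombination in progenitors of the dorsal telencephalon, from which the cerebral cortex forms. Transcriptomes of the dorsal telencephalon were compared at embryonic day 12 between 5 mutants with both copies of Rnu11 floxed and 5 controls with 1 floxed copy. The comparison asks which transcripts differ in the developing cortex when both copies of Rnu11, rather than 1, are floxed. Both groups carried Emx1-Cre, per the labels, so the floxed copy of the controls could recombine too. Levels and changes are therefore relative to these controls, and no library with intact Rnu11 was measured. The labels do not say that each library came from a separate embryo, so p-values by limma and by permutation measure the spread between these libraries. Roughly estimated depths lay between 9650000 and 21300000 fragments, and between 13092 and 14229 genes reached 1 FPKM in a library.

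The libraries fell into a pair of sets that crossed genotype. Control 5, mutant 4 and mutant 5 formed the second set, and control 1 to control 4 with mutant 1 to mutant 3 the first. The sets differed in short non-coding RNAs and in the mean log2 levels of some lists of protein-coding genes. G2 and M phase genes lay at 5.455 to 5.694 in the second set and 4.96 to 5.261 in the first. Mitochondrially encoded genes lay at 10.18 to 10.26 and 8.997 to 9.97. Other lists, such as radial glial markers, overlapped between the sets. Rnu12, the U12 small nuclear RNA, lay at 487 to 688 FPKM in the second set and at 5.91 to 33.8 FPKM in the first. Rny1, a Y RNA, lay at 137459 to 257420 FPKM in the second set against 40157.9 to 93172.5 FPKM in the first, and Rpph1, the RNA of ribonuclease P, at 27367.8 to 40837.3 FPKM against 89243.4 to 138947 FPKM. Values within the sets are given for Rnu11, for some of the named genes and for the lists that passed. The second set holds 1 control, so it gives values without a spread of its own in that group.

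Rnu11 was lower in each of the 5 mutant libraries than in any control. It averaged 2283 ± 352.5 FPKM in controls (SD, n = 5) and 892.3 ± 457.6 FPKM in mutants (SD, n = 5), which is 39.1% of the control level (exact two-sided permutation test, p = 0.00794, the smallest that 5 against 5 can give). The gene (ENSMUSG00000077323.1, 134 bases) lies on chromosome 4 from 132270080 to 132270213 in GRCm38 and overlaps no other annotated gene of the files. In the first set the level was 24.7% of control, with 565.4 ± 128.5 FPKM in mutants (SD, n = 3) and 2287 ± 406.9 FPKM in controls (SD, n = 4). In the second set it was 61.0% of control, with 1383 FPKM in mutants and 2266 FPKM in the control. The log2 difference was -1.50 (SE 0.31), and with adjustment over all tested genes it did not pass the threshold (limma, adjusted p = 0.118). With the library set as a term it was -1.65 (adjusted p = 0.00853), and without mutant 4 it was -1.68 (adjusted p = 0.0494).

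**Figure D1:**
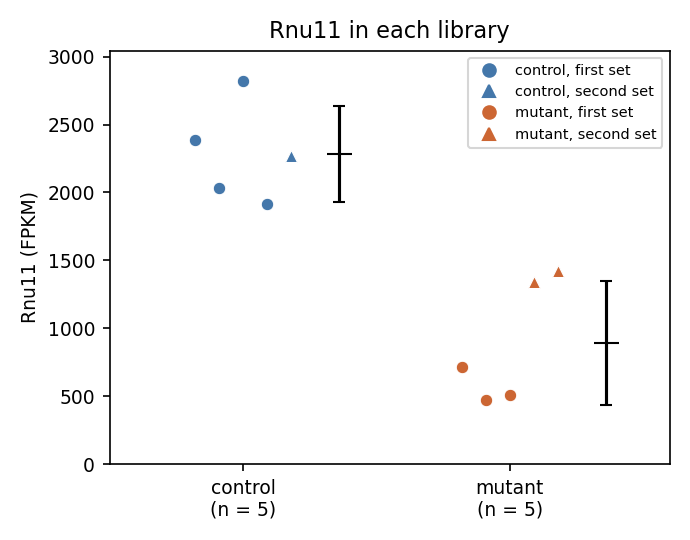
Rnu11 level in FPKM (vertical axis) in each of the 5 control and 5 mutant libraries. Circles are libraries of the first set, triangles those of the second, and bars give the mean and SD. The 5 mutant values, from 472.8 to 1421 FPKM, all lie below the lowest control value of 1913 FPKM.

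Spc24 and Lage3 had the smallest adjusted p of the genes that fell in mutants. Spc24 (chromosome 9, 21755442 to 21760303), a subunit of the kinetochore complex that binds spindle microtubules, fell from 32.4 ± 3.06 to 12.8 ± 1.12 FPKM (SD, n = 5 per group), a log2 difference of -1.28 (SE 0.10, adjusted p = 0.000375). Lage3 (chromosome X, 74351276 to 74353618), part of the KEOPS complex that modifies tRNA, fell from 41.3 ± 3.76 to 19.4 ± 1.86 FPKM (log2 difference -1.05, SE 0.10, adjusted p = 0.00157). Dap3, a protein of the small subunit of the mitochondrial ribosome, fell from 58.8 ± 6.20 to 33.4 ± 2.84 FPKM (log2 difference -0.80, adjusted p = 0.0152). Coa3, an assembly factor of cytochrome c oxidase, fell from 47.2 ± 5.11 to 27.3 ± 4.12 FPKM. Sms, the enzyme that makes spermine, fell from 26.5 ± 3.93 to 14.9 ± 1.95 FPKM. Fam96b, which acts in cytosolic iron-sulfur protein assembly, fell from 25.1 ± 2.86 to 15.1 ± 1.83 FPKM, and Eif3i, a subunit of a translation initiation factor, from 208.8 ± 15.4 to 135 ± 9.86 FPKM (adjusted p = 0.0374 for Coa3 and 0.0376 for the other 3 genes).

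Genes that rose included targets of the transcription factor p53. Eda2r (chromosome X, 97333840 to 97377216), a receptor of the tumour necrosis factor receptor family, rose 6.52 times, from 2.24 ± 0.493 to 14.6 ± 6.53 FPKM (SD, n = 5 per group, log2 difference 2.16, SE 0.29, adjusted p = 0.017). Ccng1, which encodes cyclin G1, rose from 23.1 ± 6.03 to 68.0 ± 21.7 FPKM (log2 difference 1.49, SE 0.23). Aen, a nuclease that acts in apoptosis, rose from 9.10 ± 1.95 to 18.9 ± 3.62 FPKM and Trp53inp1, a nuclear protein induced by p53, from 11.6 ± 1.80 to 22.6 ± 4.12 FPKM. Ano3, a membrane protein of the anoctamin family, rose from 0.808 ± 0.273 to 7.58 ± 4.07 FPKM, Phex, an endopeptidase of phosphate metabolism, from 0.417 ± 0.197 to 2.89 ± 0.992 FPKM, and Spag1, which acts in the assembly of ciliary dynein arms, from 1.04 ± 0.250 to 2.64 ± 0.418 FPKM. Ccdc84, also known as Cenatac, a protein of the minor spliceosome, rose from 2.92 ± 0.970 to 7.32 ± 0.480 FPKM (log2 difference 1.11, SE 0.15, adjusted p = 0.0155). Its span overlaps that of Rps25 on the opposite strand, and Dap3, Ano3, Coa3 and Fam96b also overlap a gene on the other strand, so their levels are less certain.

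In all, 21 of 13522 tested genes passed the threshold, 12 higher and 9 lower in mutants (limma), and 1185 genes had an unadjusted p under 0.05. The 6 called genes outside the naming rule were Gm20695, 2610002M06Rik, Gm14680, Hmgn2-ps1, Gm23547 and the antisense RNA A730090N16Rik, listed here after their values were seen. The median of all tested genes was 0.11 on the log2 scale, and rescaling the libraries to a common median ratio, which brought it to 0.02, gave 11 higher and 18 lower genes. Quantile normalization brought it to -0.01 and gave 13 higher and 22 lower. Groups did not overlap for 206 genes higher and 51 lower in mutants, or 1.52% and 0.377% of those tested, where chance gives 0.397%. These overlap counts used values that were not rescaled, so the shift of all tested genes by 0.11 enters them. With the library set as a term 74 genes passed, 44 higher and 30 lower, and all 21 genes called without the term were among them. In the first set alone 101 genes passed, 18 of them shared with the 21. The second set, with its single control, is given by log2 differences, which were -1.30 in the first and -1.32 in the second set for Spc24, -1.10 and -1.01 for Lage3, -0.79 and -0.70 for Dap3, 2.61 and 1.51 for Eda2r, 1.88 and 0.74 for Ccng1, 2.68 and 1.06 for Ano3, 1.19 and 0.46 for Aen and 1.077 and 0.437 for Trp53inp1. The count was 2 without control 1, control 2, mutant 2 or mutant 3, and 4 without control 3, 9 without mutant 1, 10 without mutant 5, 11 without control 4, 26 without mutant 4 and 79 without control 5. Spc24 and Lage3 passed in all 10 of these fits (highest adjusted p = 0.00345 and 0.0111), Dap3 in 6, and the other named genes in 1 to 5, with adjusted p up to 0.159. Spc24 and Lage3 were the genes called at an adjusted p of 0.01, and with the Y-linked level as a covariate 2 genes passed.

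**Figure D2:**
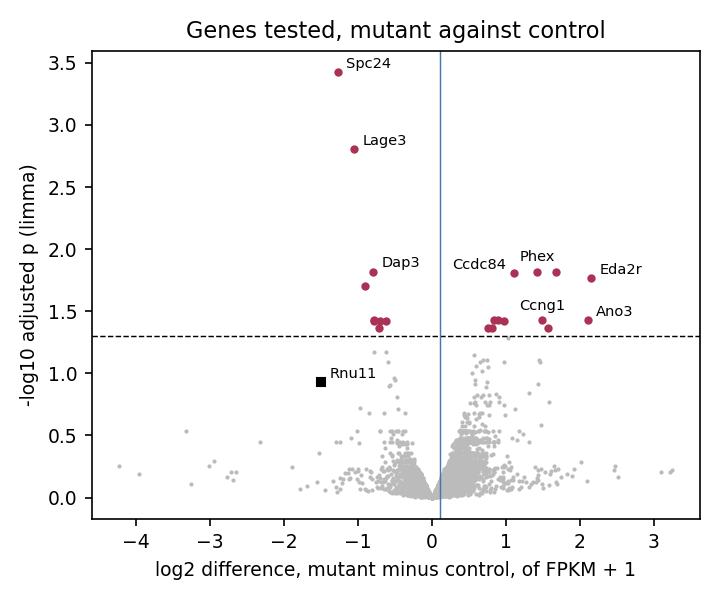
Log2 difference between mutants and controls of FPKM + 1 (horizontal axis) against -log10 of the limma adjusted p (vertical axis) for the 13522 tested genes. Red points are the 21 genes past the threshold (dashed line), the black square is Rnu11 and the blue line marks the median of all genes at 0.11; Spc24 and Lage3 stand above the other called genes.

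**Figure D3:**
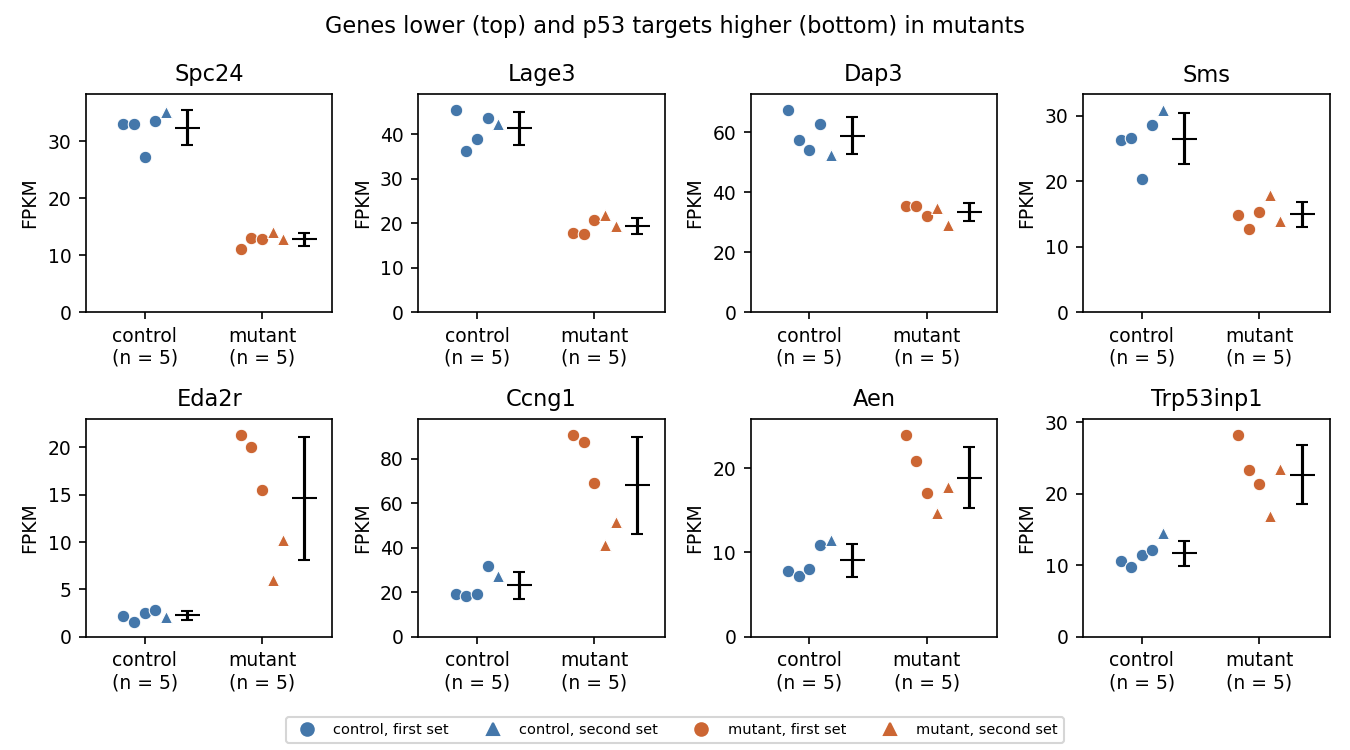
FPKM per library (vertical axes) of 4 genes that fell and 4 p53 targets that rose, with mean and SD. Circles are first-set and triangles second-set libraries; Spc24 lies at 11 to 14.2 FPKM in the 5 mutants, while Eda2r lies at 15.5 to 21.3 FPKM in the 3 first-set mutants and at 5.95 and 10.2 FPKM in the second-set mutants.

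Genes known to hold a minor intron lay lower in mutants relative to all tested genes, though not between the groups in their own level. Of the 37 genes of the list 34 were tested, and 23 lay below the median of all genes. The median of the list was -0.09 relative to all genes (camera, adjusted p = 0.000751; adjusted p = 0.914 with an estimated correlation). The list's own median log2 difference was 0.02, with 20 of 34 members above 0, and its mean level was 3.748 ± 0.196 in controls and 3.715 ± 0.0405 in mutants (SD, n = 5; exact two-sided permutation test, p = 0.706; fry, adjusted p = 0.765). Controls 1 to 3 lay at 3.568 to 3.643, below each mutant (3.675 to 3.770), and controls 4 and 5 at 3.913 and 4.001, above each mutant. Spc24 was the member that passed over all genes tested. Adjusted over the list alone, 3 members were lower and 1 higher. The lower ones included Spc24 and Polr2e, a subunit shared by the RNA polymerases, at 61.4 ± 5.56 FPKM in controls and 39.8 ± 5.34 in mutants. The higher one was the kinase gene Mapk8, at 48.0 ± 6.71 and 66.1 ± 8.15 FPKM. Mapk14 and E2f5 lay at log2 differences of -0.34 and -0.41, and Stk11, Mapk9, Ints10 and Ints4 at 0.33, 0.41, 0.20 and 0.24, without passing.

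The share of called genes in the minor-intron list was above that of other genes for lower calls. It was 1 of 34, Spc24, against 7 of 11205 other intron-containing protein-coding genes (Fisher's exact test, p = 0.024), and 0 of 34 against 9 for higher calls. With the library set as a term it was 4 of 34 against 18 for lower calls (Fisher's exact test, p = 4.91e-07), with Spc24, Polr2e and E2f5 among them. The other genes were not searched for minor introns, so they may include genes that hold one. Of 10000 random lists matched on expression and number of introns, 24 had a median as low. These draws and Fisher's test treat genes as independent of each other, so neither measures the spread between libraries. Relative medians were -0.10 in the first set and -0.12 in the second. The list's call was lost without control 5 (relative median -0.06, adjusted p = 0.0669).

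Components of the minor spliceosome did not move together. Of the 16 tested, Ccdc84 rose, and the list as a whole did not pass (relative median 0.09, camera, adjusted p = 0.428). Adjusted over the list alone, Ccdc84 and Snrnp48 were higher and Rnu11 lower. Snrnp48, a protein of the U11/U12 particle chosen here after its values were seen, lay at 6.67 FPKM in controls and 13.1 FPKM in mutants and passed over all genes with the library set as a term (adjusted p = 0.00815). Genes of the major spliceosome showed no call among 34 tested, over all genes or over the list alone (relative median 0.03, camera, adjusted p = 0.493), with Snrnp200 at a log2 difference of 0.46 and Snrpa at 0.39. Of 7 short non-coding RNA comparators 0 passed (adjusted p = 0.152), and the list's median and mean differed in sign (0.07 and -0.03). Terc and Rpph1 lay at log2 differences of -0.66 and -0.40. The list's relative median was -0.43 in the first set and 0.44 in the second (camera of the difference between sets, adjusted p = 0.00208; adjusted p = 0.982 with an estimated correlation).

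The p53 targets rose as a group. Of 37 tested members 33 lay above the median of all genes, with a relative median of 0.26 (camera, adjusted p = 4.88e-15; adjusted p = 0.609 with an estimated correlation). Eda2r, Ccng1, Trp53inp1 and Aen passed over all genes, and 18 members were higher and 0 lower adjusted over the list alone. These included, chosen after their values were seen, the cell cycle inhibitor Cdkn1a, at 2.32 FPKM in controls and 5.22 in mutants, the apoptosis genes Bax, at 45.03 and 67.5, and Bbc3, at 0.925 and 2.39, and Trp53 itself, at 12.5 and 16.3. The mean level of the list was 3.096 ± 0.137 in controls and 3.63 ± 0.228 in mutants on the log2 scale (SD, n = 5), higher in each mutant than in any control (exact two-sided permutation test, p = 0.00794, adjusted over the lists 0.107). The relative median was 0.37 in the first set and 0.18 in the second.

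Genes of the apoptosis machinery list showed 0 calls among 26 tested over all genes and over the list alone (camera, adjusted p = 0.662, relative median -0.02). Cflar, an inhibitor of caspase 8, lay at 4.85 ± 0.958 FPKM in controls and 6.32 ± 0.218 in mutants (SD, n = 5), without overlap but short of the threshold (adjusted p = 0.457), and Bmf at a log2 difference of 0.27. DNA damage response genes had 0 calls among 35, with Xrcc5 at -0.46 and Fanci at 0.28, and the list passed with the library set as a term (camera, adjusted p = 0.0203; adjusted p = 0.921 with an estimated correlation). Integrated stress response genes had 0 among 20, with Sesn2, also a p53 target, at 1.24 and Ddit3 at 0.36. The unfolded protein response had 0 among 16, with Herpud1 at 0.34 and Pdia6 at 0.24, and interferon-stimulated genes 0 among 8, with Irf9 at 0.18. Without the term the adjusted p of these 4 lists by camera ran from 0.168 to 0.817.

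Markers of early excitatory neurons stood higher in mutants relative to all genes. All 28 neuron markers lay above the median of all genes, with a relative median of 0.27 (camera, adjusted p = 7.35e-05; adjusted p = 0.865 with an estimated correlation). The list's mean level was 3.547 ± 0.165 in controls and 3.933 ± 0.285 in mutants (SD, n = 5; exact two-sided permutation test, p = 0.0476, adjusted over the lists 0.429; fry, adjusted p = 0.247). No member passed over all genes and 1 did adjusted over the list alone, Snap25, a protein of synaptic vesicle fusion, at 2.14 ± 0.293 FPKM in controls and 3.98 ± 1.07 in mutants. Gap43, a growth cone protein, lay at 27.2 ± 6.85 and 40.2 ± 5.45 FPKM. With the library set as a term 2 members passed over all genes and 15 over the list alone, and relative medians were 0.37 in the first set and 0.13 in the second. Control 4, at a list level of 3.83, lay above the 4 other controls (3.40 to 3.54) and above mutants 4 and 5 (3.61 and 3.66). Without control 5 the list's call was lost (relative median 0.25, adjusted p = 0.0655). Control 4 also stood above all other libraries for ventral telencephalon markers, at 3.96. Whether ventral tissue added to the neuron levels of any library was not tested.

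Of 30 radial glial markers 0 passed over all genes or over the list alone (camera, adjusted p = 0.817), with Pax6 at a log2 difference of 0.30 and Fabp7 at 0.35. Of 17 intermediate progenitor markers 0 passed over all genes and 1 over the list alone, Mfap4, at 5.65 ± 0.626 FPKM in controls and 8.18 ± 0.973 in mutants. Gadd45g lay at 0.33, and the list by camera at an adjusted p of 0.172. The list's mean level was 3.361 ± 0.0696 in controls and 3.532 ± 0.0591 in mutants (SD, n = 5). It was higher in each mutant than in any control (exact two-sided permutation test, p = 0.00794, adjusted over the lists 0.107, and fry, adjusted p = 0.049). These levels were not rescaled, and the median of all tested genes itself lay at 0.11. Relative to it the list's median was 0.07. Of 11 Cajal-Retzius markers 0 passed (adjusted p = 0.662), with Reln at 0.39 and Ebf2 at 0.31. Of 32 patterning genes 0 passed (adjusted p = 0.662), with Lmo3 at 0.55, and the list's median and mean differed in sign (-0.03 and 0.00275).

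S phase genes lay lower relative to all genes, with 23 of 30 below the median of all genes and a relative median of -0.09 (camera, adjusted p = 0.0121; adjusted p = 0.931 with an estimated correlation). The list's own median log2 difference was 0.01, with 20 of 30 genes above 0, and its mean level was 5.025 ± 0.231 in controls and 5.031 ± 0.18 in mutants (SD, n = 5; exact two-sided permutation test, p = 0.984). No member passed, over all genes or over the list alone. Tk1 lay at 40.6 ± 4.44 FPKM in controls and 32.5 ± 3.43 in mutants, and Tyms at 112 ± 10.8 and 94.6 ± 8.53. Relative medians were -0.18 in the first set and -0.09 in the second. The list's call was lost without control 5, mutant 1 or mutant 3 (adjusted p = 0.341, 0.48 and 0.179) and with the Y-linked level as a covariate (0.299). Among G2 and M phase genes Spc24, which is also in the minor-intron list, was the call over all genes and over the list alone, and the 35 genes as a list did not pass (relative median -0.04, adjusted p = 0.168), while with the library set as a term they did (adjusted p = 0.00213; adjusted p = 0.921 with an estimated correlation). Ribosomal protein genes did not pass either (36 tested, 0 called, adjusted p = 0.15), with Rps19 at 0.39 and Rplp1 at -0.58, and had relative medians of -0.09 in the first set and 0.10 in the second.

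**Figure D4:**
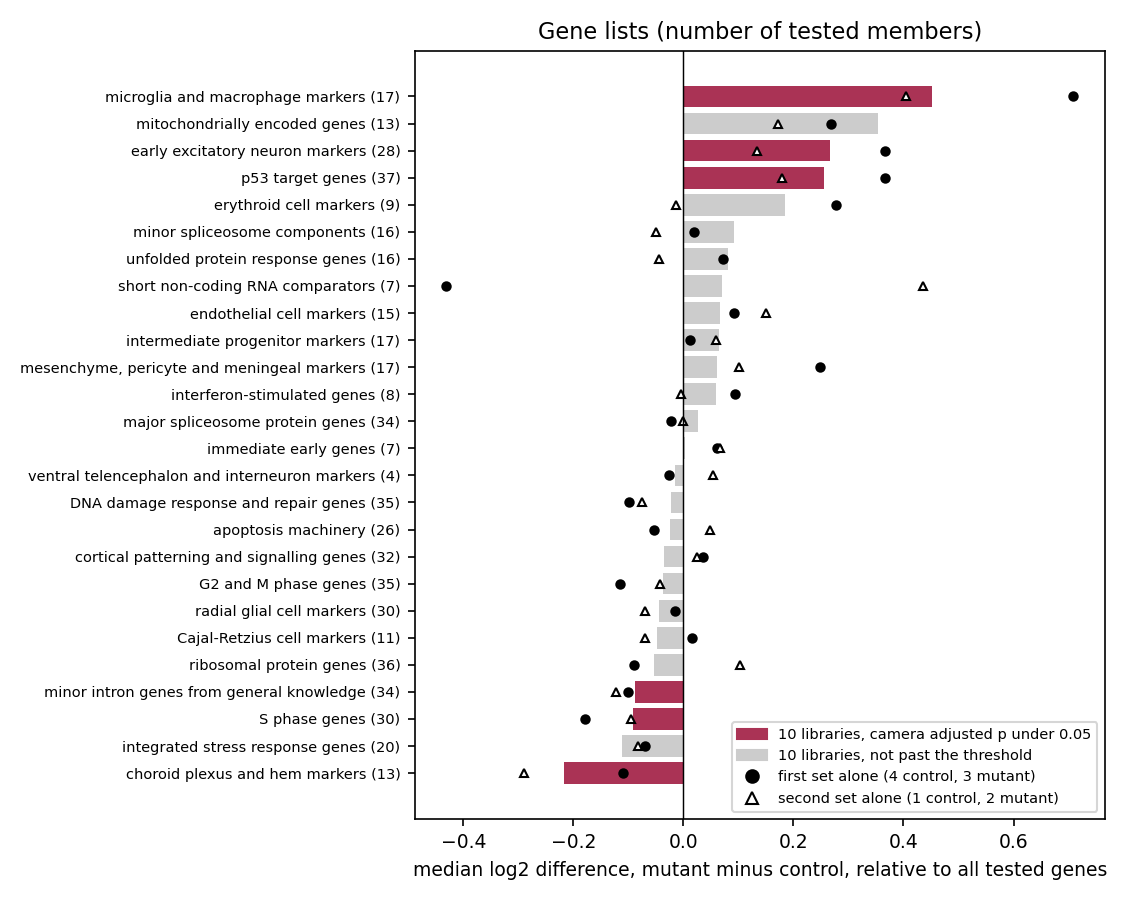
Median log2 difference of each list between mutants and controls, relative to all tested genes (horizontal axis), with the number of tested members. Bars are the 10 libraries (red where camera's adjusted p passed at the preset correlation), circles the first set and triangles the second. With an estimated correlation camera called 0 lists. The p53 targets and neuron markers lie at 0.26 and 0.27, and minor-intron genes at -0.09.

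Relative to all genes, microglia and macrophage markers stood higher in mutants and choroid plexus and hem markers lower, while neither list passed in its own level (fry, adjusted p = 0.353 and 0.543). All 17 microglia markers lay above the median of all genes (relative median 0.45, camera, adjusted p = 7.35e-05; adjusted p = 0.914 with an estimated correlation), with 0 calls over all genes and over the list alone. Fcer1g, a signalling subunit of immune receptors, lay at 4.20 ± 1.35 FPKM in controls and 7.40 ± 2.47 in mutants, and the scavenger receptor gene Mrc1 at 2.51 ± 0.573 and 4.28 ± 1.48. The relative median was 0.71 in the first set and 0.40 in the second, and 3 members passed over all genes with the library set as a term. Without control 5 the list's call was lost (relative median 0.37, adjusted p = 0.155). Choroid plexus and hem markers had a relative median of -0.22 (13 tested, 0 called over all genes or over the list alone, adjusted p = 0.000306; adjusted p = 0.609 with an estimated correlation), with Htr2c at -0.42 and Folr1 at -0.32. This median was -0.11 in the first set, where the list did not pass (adjusted p = 0.119), and -0.29 in the second.

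Markers of other cells of the dissected region did not pass. Camera gave an adjusted p of 0.716 for erythroid markers (9 tested, Hba-a1 at 0.50 and Alas2 at 0.41), 0.662 for endothelial markers (15 tested, Emcn at 0.43 and Erg at 0.31) and 0.817 for mesenchyme, pericytes and meninges (17 tested, Rgs5 at 0.32 and Cxcl12 at 0.42). For ventral telencephalon it gave 0.257 (4 tested, Zfp503 at -0.41 and Meis2 at 0.11), for mitochondrially encoded genes 0.15 (relative median 0.35, 12 of 13 above the median of all genes, mt-Nd2 at 0.64 and mt-Nd5 at 0.37) and for immediate early genes 0.774 (7 tested, Ier2 at 0.25 and Junb at 0.29). None of these lists had a call over all genes or over the list alone. Exact permutation tests of the mean levels of these lists and of the choroid plexus and microglia lists gave p from 0.0952 to 0.952, and without control 5 the mitochondrially encoded genes gave 0.0476. Xist, which marks female embryos, lay at 65.7 to 147.6 FPKM in control 1, control 2, control 3, control 5, mutant 2 and mutant 4, and Ddx3y, on the Y chromosome, at 17.1 to 23.3 FPKM in control 4, mutant 1, mutant 3 and mutant 5. The groups thus held 4 and 2 libraries with Xist.

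**Figure D5:**
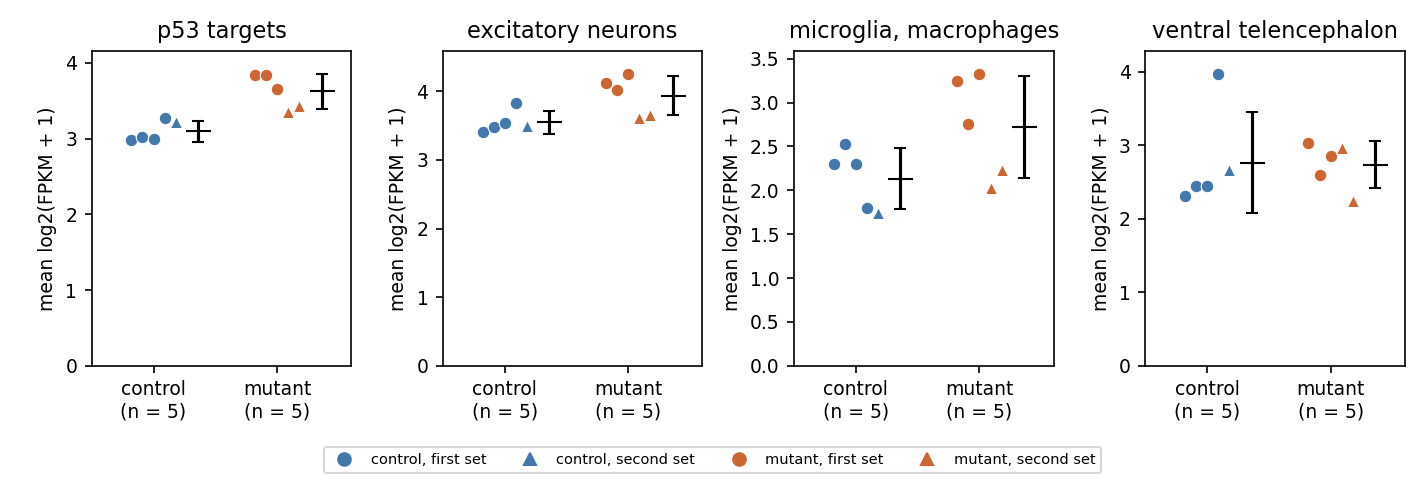
Mean log2(FPKM + 1) of 4 lists (vertical axes) in each library, with mean and SD per group. Circles are first-set and triangles second-set libraries; p53 targets are higher in each mutant than in any control, and control 4 stands at 3.96 for ventral telencephalon markers, above the other 9 libraries.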

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

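The tests of single libraries below were set before the data were seen, and the single ventral genes named were chosen after their values were seen. In 92 groups of libraries tested, 5 held a library far from the others of its group, where chance gives about 1 in 20, or 4.6. Spc24 in control 3 lay at 27.2 FPKM, against 33 to 35.2 FPKM in the other controls, and above all mutants. The mean level of minor spliceosome components in control 5 was 4.21 on the log2 scale, against 3.39 to 3.57 in the other controls. Rnu12 in control 5 lay at 688 FPKM, against 5.91 to 27 FPKM in the other controls. Both values of control 5 follow the library sets. For the minor spliceosome list mutants 4 and 5, also of the second set, lay at 4.161 and 4.174, and mutants 1 to 3 at 3.613 to 3.741. Rnu12, a member of that list, lay at 487 and 573 FPKM in mutants 4 and 5. The Cajal-Retzius list in mutant 5 lay at 2.33, against 2.62 to 2.7 in the other mutants. The ventral telencephalon list in control 4 lay at 3.96, against 2.3 to 2.66 in the other controls, with Dlx1 at 17.8 FPKM (other controls up to 2.11), Dlx2 at 11.3 (up to 1.12), Isl1 at 14.9 (up to 1.52) and Gad2 at 5.78 (up to 0.369). Mutants 1, 3 and 4 also lay above the controls other than control 4, at list levels of 3.028, 2.848 and 2.96, with Dlx1 at 6.65, 2.48 and 6.57 FPKM and Gad2 at 1.12, 0.386 and 0.923.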

How the results depend on the processing

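The tests with library sets, their combinations with rescaling and those without control 4 beside a set were chosen after seeing the data. Of the main results under alternatives, 118 kept direction and side of the threshold, or a count within 1.5 times, 33 gained a call or genes and 43 lost; for gene lists this was 622, 39 and 10, with 1 reversed, and for named genes 1622, 54 and 141.

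The count of 21 genes (12 higher, 9 lower) changed under many alternatives. It was 2 (0 higher, 2 lower) without a filter, with 26845 genes tested, and 7 were higher with at least 5 FPKM in 5 libraries. It was 2 (0 and 2) at an adjusted p of 0.01, 2 (0 and 2) with the Y-linked level as a covariate, and 9 (7 and 2) for changes of at least 2-fold. Rescaling gave 18 lower, quantile normalization 35 with 22 lower (Rnu11 -1.536, adjusted p = 0.0435), and library quality weights 995 (931 and 64; Rnu11 -1.817, adjusted p = 0.00656). With replicate number as a block 14 passed, 9 higher and 5 lower, 10 of them shared with the 21. Whether replicate numbers pair libraries stays open. Correlations between control and mutant of the same number were 0.0773, 0.155, 0.236, -0.107 and 0.521. Controls 3 and 5 correlated best with the mutant of their own number, and controls 1, 2 and 4 with another. Control 5 and mutant 5 both belong to the second library set. The cause of the changes in the count of genes was not tested beyond the number of genes tested without a filter.

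The set as a term gave 74 genes (44 higher, 30 lower), Rnu11 at -1.655 and 10 called lists. The first set alone gave 101 (82 and 19) with Rnu11 at -2.021, and the second alone 7 higher among 20, with its lone control assumed to vary like the other libraries, so these calls do not show whether the 21 genes recur. Rescaling with the set as a term gave 91 (43 and 48) with Rnu11 at -1.749. The first set rescaled gave 78 (39 and 39) with Rnu11 at -2.181, and without control 4 as well 187 (95 and 92) with Rnu11 at -2.314. There the Cajal-Retzius list stood at 0.1169 (adjusted p = 0.0468), reversed from -0.05. The cause was not tested.

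Leaving out each library in turn gave 2 to 79 genes, 0 to 68 higher and 2 to 11 lower, Rnu11 from -1.704 to -1.307 (adjusted p 0.0494 to 0.336), a minor-intron median from -0.1178 to -0.0643, 3 to 9 called lists and 0 to 1 cell type or quality check at p under 0.05. With an estimated correlation camera called 0 lists and gave the minor-intron list, at -0.08763, an adjusted p of 0.914, and fry called 2 lists. Lists that gained a call were G2 and M phase without control 3, control 4, mutant 4 or mutant 5 (adjusted p = 0.0145, 0.0487, 0.00309 and 0.00606), ribosomal proteins without control 4, mutant 4 or mutant 5 (0.000493, 0.0397 and 0.00496), short non-coding RNAs without control 4 or mutant 5 (0.0194 and 0.0338), mitochondrially encoded genes without control 2, mutant 1 or mutant 2 (0.0118, 0.0416 and 0.00135), the unfolded protein response without control 5 (0.0454) and endothelial and mesenchyme markers without control 2 (0.0411 each). Mitochondrially encoded genes also gained it by rescaling (0.0483), quantile normalization (0.000965) and the replicate block (0.0393), ventral markers without a filter (0.02), and ribosomal proteins, short non-coding RNAs and the unfolded protein response with quality weights (9.55e-05, 0.00167 and 0.043). With the set as a term these were short non-coding RNAs (0.0391), G2 and M phase (0.00213), DNA damage response (0.0203) and ribosomal proteins (0.0208), and with an estimated correlation no list passed there (lowest adjusted p = 0.556). Early neurons and microglia lost their call without control 5 (0.0655 and 0.155), S phase there too (0.341), without mutant 1 or mutant 3 (0.48 and 0.179), with the Y-linked covariate (0.299) and in the second set (0.146), and choroid plexus in the first set (0.119, rescaled 0.388, and 0.264 without control 4).

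Depth is known only as a rough estimate, so which low genes lie within counting noise was not computed. The motif rule for minor introns and its looser form were not run, since no genome sequence was used.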

Other observations

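The tests of the library sets, of dilution, scaling and short-RNA yield, and of tissue carried over were chosen only after the result was seen, while those of other splits and of embryo age were written before. All genes in the next paragraphs were chosen after their values were seen.

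With the library set as a term, further genes fell. Pde6d, a carrier of prenylated proteins, averaged 13.9 ± 2.65 FPKM in controls and 7.49 ± 2.73 in mutants (SD, n = 5; log2 difference -0.98, adjusted p = 0.00127). Arl2, a small GTPase of the same pathway, lay at 15.3 and 10.4 FPKM (-0.52, adjusted p = 0.0473). Lsm5, of the ring that binds U6 RNA and decaying mRNA, fell (log2 difference -0.76, adjusted p = 0.0115), as did the decapping enzyme gene Dcp2 (-0.63, adjusted p = 0.0391) and Sptssa, a subunit of the enzyme that starts sphingolipid synthesis (-0.62, adjusted p = 0.00961). Lower too were the kinase gene Mapk11 (-0.61, adjusted p = 0.0465), Fig4, a lipid phosphatase (-0.53, adjusted p = 0.0365), and Xrcc5, which acts in the joining of DNA ends (-0.55, adjusted p = 0.046).

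Genes that rose in the same fit included further p53 targets. Phlda3, an inhibitor of Akt signalling, rose from 2.14 ± 0.704 to 6.69 ± 4.17 FPKM (SD, n = 5; log2 difference 1.35, adjusted p = 0.0115), Ephx1 by 1.13 (adjusted p = 0.0111), Plk2 by 0.89 (adjusted p = 0.0365) and Gtse1 by 0.76 (adjusted p = 0.0438). The kinase gene Mapkapk3 rose from 1.15 ± 0.417 to 3.98 ± 1.93 FPKM (1.28, adjusted p = 0.00853) and Arap2 by 1.56 (adjusted p = 0.0198). Microglial C1qa rose from 6.80 ± 3.36 to 14.5 ± 7.28 FPKM (1.25, adjusted p = 0.0089) and Fcrls from 4.18 ± 1.57 to 10.1 ± 6.07 FPKM (1.21, adjusted p = 0.0149). The neuronal genes Snap25 and Rbfox3 rose by 0.72 and 0.74 (adjusted p = 0.0231 and 0.0391).

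Other splits of the libraries into 5 and 5, 100 of the 126 possible, were run as the real one was. As many genes passed in 2 of 100 splits (real 21, highest other 591) and in 1 of 100 with the set as a term (real 74, highest other 9). The real split is counted in each, and there was no adjustment over the patterns compared. Chance is thus unlikely for both counts but not excluded. The split with 591 genes put the second set in a single group, which points to a structure of the samples, and with the set as a term it gave 2. The other 15 splits with the second set together gave 0 to 9, so that feature alone does not account for the 591. On -log10 p by camera chance is likewise unlikely for p53 targets (1 of 100, real 15.7, highest other 9.46). Chance stays open for minor-intron genes (5 of 100, real 3.84, highest other 4.21), neurons (11, 5.07 and 9.43), S phase (45, 2.55 and 11.5), choroid plexus (15, 4.33 and 6.97), microglia (37, 5.17 and 20.6) and the number of called lists (70, 6 and 14).

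The smaller difference of Rnu11 and p53 targets in the second set was weighed first. The difference between sets was 1.31 log2 for Rnu11 (SE 0.345, adjusted p = 0.535, with 0 genes at adjusted p < 0.05 and 1227 at unadjusted p < 0.05 by limma) and passed for p53 targets by camera (adjusted p = 0.000179; adjusted p = 0.982 with an estimated correlation). Rescaling did not shrink the Rnu11 difference, which was then 1.54. This argues against scaling of the values for Rnu11, though the difference rests on the single control of the second set. Dilution by tissue that kept Rnu11 stays open. Of genes called lower in the first set, 3 choices were tried after their values were seen. A choice of 15 genes kept a median of 0.734 of their loss (bootstrap interval 0.584 to 0.798), with single shares from -1.037 to 0.926. A choice of 18 genes kept 0.654 (lower bound 0.25) and 10 protein-coding genes 0.762, while Rnu11 kept 0.458. The 14 p53 targets called higher in the first set kept a median of 0.426 of their rise, with shares from 0.099 to 1.141. Choosing genes by their call in the first set by itself lowers the share expected in the second. Each share also rests on the single control of the second set. Another yield of short RNAs stays open too, since Rnu11 in control 5 was 0.991 of the other controls, a single library, and in second-set mutants 2.45 of the first-set mutants.

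For neuron markers, an older stage of the mutant embryos stays open. Genes that fall with age (5 tested of 7) had a relative median of -0.0437, with 3 of 5 below 0 and values from -0.235 to 0.133. Unequal numbers of mutants and controls in the sets is argued against, since with the set as a term the list's median was 0.36 (camera, adjusted p = 9.71e-09; adjusted p = 0.556 with an estimated correlation) and 15 of 28 members passed over the list alone. Within the first set the list lay at 4.024 to 4.25 in mutants and 3.401 to 3.829 in controls (exact two-sided permutation test, p = 0.0571). More or earlier neurons in mutants was not tested apart from these.

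For microglia markers, blood, vessel or meningeal tissue in the mutant dissections stays open. The list's excess over those of these tissues was 0.388 log2 higher in mutants (SE 0.227, exact two-sided permutation test, p = 0.167), and alone 0.313 over erythroid (p = 0.484), 0.418 over endothelial (p = 0.111) and 0.432 over mesenchymal and meningeal markers (p = 0.00794). Unequal numbers in the sets is argued against by the first set alone, where the list lay at 2.756 to 3.324 in 3 mutants and 1.795 to 2.532 in 4 controls (exact two-sided permutation test, p = 0.0286). The median of 0.404 in the second set rests on a single control and does not weigh here. A response of microglia to the mutant tissue was not tested apart from these.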
